A study of Arabidopsis thaliana with 24 samples.

How the data were processed

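Poly-A RNA of the oldest leaf was sequenced as single reads in 24 libraries: 3 for each of the parents Bur-0 and Col-0 and for each pool type (early- and late-flowering recombinant lines) at days 14 and 28, per the labels' protocols. The deposited table holds raw read counts per locus, 1 column for each library, per the file headers and the labels. The submitters' processing notes name FastQC, Bowtie2, TopHat and Cufflinks without versions and the build TAIR10. The counting tool, the strand setting and the treatment of reads that match several loci are not given in the sources used here. The values were checked to be whole numbers, and 0 columns were left out. The table has 21646 loci with a total of at least 20 counts each, of which 97 are of the chloroplast and 57 of the mitochondrion, 161 have the same counts as another locus and 5783 overlap another locus. Where genes overlap, or have identical counts, their values are uncertain. Among the named genes this applies to FRI, MCM7, LLP1, UGT74C1, PSBR, AT4G27595, AT5G24240, FKF1, COR15B, SARD4, FLS2, CYP71A13, SPL5, GAPA1, CA1, AT1G25098, AT1G25175, AT1G24822, AT1G25097, AT2G04378, AT1G58684, AT1G58983, AT1G25211, AT1G25150, AT1G24800, AT1G17610, LNK1, CDKB2-1, CYCD3-1, EDS5 and SAL2. Gene names, descriptions and coordinates come from the NCBI annotation of assembly TAIR10.1, matched by locus ID for 98.9% of loci, and coordinates are 1-based.

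Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood F-tests), in 1 model of the 12 pool libraries and 1 of the 12 parental libraries, each with 4 group means. This tested 18786 genes in the pools and 18885 in the parents. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 10 comparisons were late against early pools and Bur against Col at each day, day 28 against day 14 in each of the 4 materials, and both interactions with day. CPM use the TMM-scaled library sizes of the same model, and log2 CPM add a prior count of 2. edgeR p-values measure spread between libraries, but Fisher and camera p between genes. Folds against 0 counts are bounds against a floor of 3 over the group. Ratios with 1 to 3 counts have exact 95% binomial intervals. Both cover counting error only. The scripts were tested on simulated data with 3 libraries per group. Of 100 genes each with a log2 change of 1 and 2, 17% and 84% were recovered for late against early pools at day 14 (18727 genes), 20% and 85% at day 28 (18745 genes), 35% and 78% for Bur against Col at day 14 (18824 genes) and 31% and 86% at day 28 (18837 genes), with 4, 2, 1 and 8 false calls.

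Gene lists were fixed by locus ID before the data were examined, as were the comparisons, most alternatives and the rule for named genes. They cover salicylic acid and systemic acquired resistance, pattern-triggered immunity, camalexin, jasmonate, aliphatic and indole glucosinolates, floral activators, floral repressors, leaf senescence, photosynthesis, heat shock, flavonoids, cold and abscisic acid response, the circadian clock, phosphate starvation, cell division, and markers of the shoot meristem, flower, root, stomatal lineage and vascular tissue. Ribosomal protein and NLR genes were taken by rule from the gene descriptions. Of 416 list members, 0 were dropped because their symbol belongs to another locus. The 20 lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation. The rule named, for each comparison of pools or parents at a day, the 6 higher and 6 lower called genes of largest log2 fold change with a mean log2 CPM of at least 1 and no overlap of the groups, which chance gives in 10% of genes for 3 against 3. It added up to 3 members of smallest adjusted p of each called list and of the salicylic acid and flowering lists. For changes with age and interactions it took 4 and 4 genes, and up to 2 members of each called list. PR1, PR2, PR5, ICS1, FLC, FRI, FT, SOC1, SVP, MAF2 and SAG12 were included in any case if the table held them, which it did not for SAG12, and windows by the 5 smallest p with the list genes inside them.

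Overlaps of calls were tested with 1-sided Fisher exact tests. Called genes were counted in windows of 1 Mb with at least 20 tested genes. Slopes through the origin were fitted in windows of 2 Mb with at least 10 genes that were called between the parents at a log2 fold change of at least 1, and compared with 1000 shuffles of genes among windows. Alternatives were DESeq2 1.42.0, median-of-ratios factors, no filter on low counts, only the 6 libraries compared, all 24 libraries in 1 model, a replicate block for the parents, other window sizes, an expression minimum, and leaving out each library in turn. Other splits of the same libraries were also fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.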

Results

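Messenger RNA of the oldest leaf of Arabidopsis thaliana was sequenced in 24 libraries, which form 8 groups of 3. The accessions Bur-0 and Col-0, parents of a population of 278 recombinant inbred lines, were sampled at days 14 and 28. Leaves of 12 plants were pooled per parent and day (groups Bur_14d, Col_14d, Bur_28d and Col_28d). From 40 lines chosen in both tails of flowering time, pools of 13 early- or 13 late-flowering lines were made at both days (early_14d, late_14d, early_28d and late_28d). Libraries are named by group and number (1 to 3 in each parental group, 1 to 12 over the pools). The 12 pools of 13 must share lines. The labels do not say which, the hour of harvest, or whether a parent's libraries came from separate plants. Pool p-values thus do not measure spread between lines. Totals ran from 13915307 counts (late_28d replicate 11) to 19592597 (early_14d replicate 1). The 10 most abundant genes took 11.8% to 18.6% of a library.

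Parental genotype and day separated most libraries. The principal component of largest variance (27.5%, over 15687 genes) placed Bur libraries at -69.5 to -42.5 and Col libraries at 28.7 to 69.2. Late pools lay at -41.6 to 0.975 and early pools at 7.73 to 33.3, so that late pools were nearer to Bur. On the next component (20.1%), day 14 and day 28 parted in Bur and in both pools but overlapped in Col. Replicates correlated across genes with r of 0.880 to 0.982, where genes are not independent replicates. The spread was widest in late_28d, with a median SD of log2 CPM of 0.435 against 0.182 to 0.243 in the other groups. There, late_28d replicate 11 stood apart at -71.0 on a further component (15.6% of variance).

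**Figure D1:**
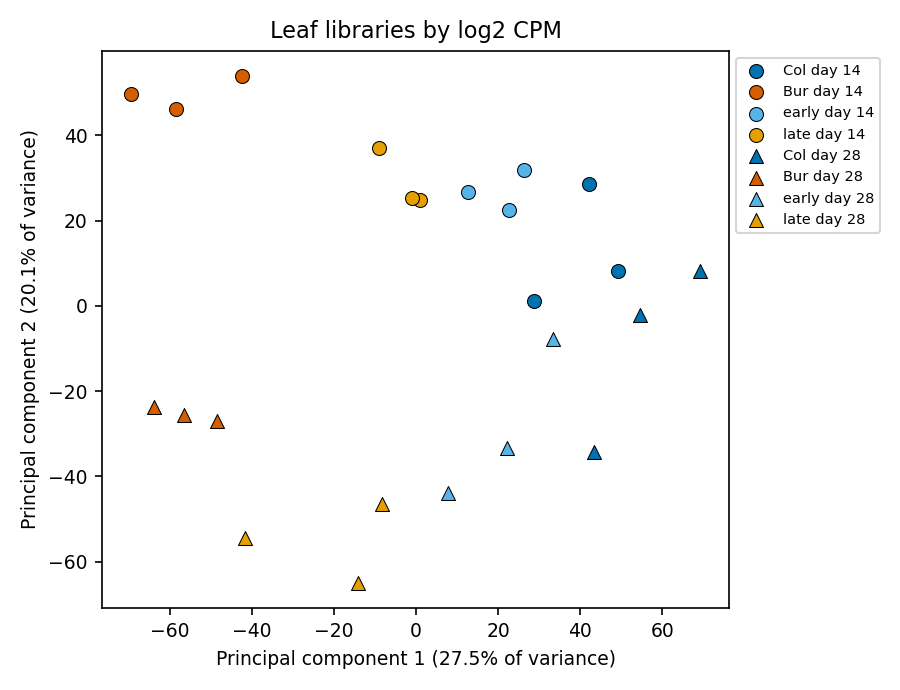
Each point is 1 of the 24 libraries, with the 2 components of largest variance of log2 CPM on the axes (27.5% and 20.1%), colour by material and shape by day. Bur libraries lie at -69.5 to -42.5 and Col libraries at 28.7 to 69.2 on the horizontal axis.

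The comparison of late with early pools asks which leaf transcripts differ between lines that flower late and lines that flower early. At day 14, FLC, which encodes a MADS-box repressor of flowering, stood at 30.1 ± 1.40 CPM in late pools and 7.36 ± 1.22 CPM in early pools (mean ± SD, n = 3). Its log2 fold change was 2.03 ± 0.22 (± SE here and below; edgeR adjusted p = 0.00466; chromosome 5, 3173382 to 3179448). AT5G11580, of the family of regulators of chromosome condensation, was also higher (log2 fold change 1.66 ± 0.23, edgeR adjusted p = 0.0382). Lower in late pools were BETA-VPE, which encodes a vacuolar processing enzyme (log2 fold change -3.22 ± 0.35, edgeR adjusted p = 0.00466), and the TIR-NBS-LRR resistance gene AT1G63880 (log2 fold change -2.76 ± 0.36, edgeR adjusted p = 0.0220). The protein kinase gene AT1G65190 was lower as well (log2 fold change -1.57 ± 0.17, edgeR adjusted p = 0.00466). BETA-VPE, AT1G63880 and AT1G65190 start at 23223874, 23712216 and 24215591 of chromosome 1. The immune markers PR1 (edgeR adjusted p = 0.444, 0.276 to 0.828 over its alternatives), PR2 and PR5, whose products accumulate with salicylic acid, were not called, nor were ICS1, SOC1, SVP, MAF2 and FRI.

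Flavonoid and anthocyanin genes were lower in late pools at day 14 as a group, with 0 higher and 0 lower of 11 (0 and 5 adjusted over the list alone). For this list, the median log2 fold change was -0.96 (camera adjusted p = 0.000359, adjusted p = 0.457 with an estimated correlation). Aliphatic glucosinolate genes make sulfur-containing defence compounds. In late pools they were higher as a group, with 0 higher and 0 lower of 22 (0 and 0 over the list alone). The list had a median log2 fold change of 0.41 (camera adjusted p = 0.00518, adjusted p = 0.825 with an estimated correlation). Phosphate starvation genes were lower as a group, with 0 higher and 0 lower of 6 (0 and 0 over the list alone). The median was -0.68 (camera adjusted p = 0.0496, or 0.457 with an estimated correlation). Salicylic acid and systemic acquired resistance genes were not called, with 0 higher and 0 lower of 40 (0 and 0 over the list alone). Tested members had a median of -0.49 (camera adjusted p = 0.0688, or 0.825 with an estimated correlation). This list was called without early_14d replicate 2 (9.82e-06) and late_14d replicate 4 (0.00223), with the camera adjusted p in brackets for lists here and below. Circadian clock genes had 0 higher and 0 lower of 18 (6 and 3 over the list alone). With calls kept, medians moved to -1.48 for flavonoids without a filter on low counts.

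edgeR called 5 of 18786 genes at day 14, 2 higher and 3 lower. At an unadjusted p under 0.05 there were 2107, against 939.3 by chance, and DESeq2 called 371. The edgeR count was 2 without early_14d replicate 1 or 2, 9 without late_14d replicate 4, and 0 without late_14d replicate 5 or 6. FLC lost its call without early_14d replicates 1 (0.0571) and 2 (0.0513) and late_14d replicates 5 (0.0681) and 6 (0.0725), with the edgeR adjusted p in brackets for genes here and below. AT5G11580 lost it without early_14d replicates 1 (0.196) and 2 (0.139) and late_14d replicates 5 (0.170) and 6 (0.125). AT1G63880 lost it without early_14d replicates 1 (0.103) and 2 (0.0917) and late_14d replicates 4 (0.0686), 5 (0.103) and 6 (0.125). AT1G65190 lost it without late_14d replicates 5 (0.0681) and 6 (0.0725), and BETA-VPE without late_14d replicates 5 (0.0681) and 6 (0.0725). The list calls ended without early_14d replicate 3 (0.0591) and late_14d replicate 6 (0.0775) for aliphatic glucosinolates. For phosphate starvation they ended without early_14d replicate 1 (0.418; median -0.19) and late_14d replicates 4 (0.0844) and 6 (0.0775). With all 24 libraries in 1 model, both list calls ended (0.112 and 0.0991). With only the 6 libraries compared, AT5G11580 (0.0566) and BETA-VPE (0.0555) were not called.

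At day 28, the pools differed in many genes, and FLC was again higher in late pools (24.2 ± 4.49 against 6.16 ± 1.49 CPM, log2 fold change 1.97 ± 0.22, edgeR adjusted p = 0.00337). Largest increases (log2 fold change) were in AT1G27020 (5.52 ± 0.82), AZI1 (5.09 ± 0.75), NRT2.6 (4.70 ± 1.01), MIOX2 (4.66 ± 0.79) and AT4G21870 (4.31 ± 0.75). Largest decreases were in AT1G10640 (-4.71 ± 0.66), ZW9 (-4.45 ± 0.80), UGT76B1 (-4.35 ± 1.02), AT1G76960 (-4.00 ± 0.87), ADS1 (-3.21 ± 0.49) and AT4G27595 (-3.15 ± 0.41). UGT76B1 encodes a glucosyltransferase of immune signal molecules, ADS1 a fatty acid desaturase and AT1G10640 a pectin lyase-like protein. The called genes given here had edgeR adjusted p of 0.00337 to 0.0133. edgeR called 4219 of 18786 genes, 2187 higher and 2032 lower, with spread shared by all pools. It called 1063 with only the 6 libraries compared. The call of UGT76B1 ended without early_28d replicate 7 (0.0507). Of the 4219, 2433 differed by at least 2-fold (1077 higher and 1356 lower).

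Salicylic acid and systemic acquired resistance genes were lower in late pools at day 28, with 1 higher and 14 lower of 40 (1 and 17 over the list alone). This gave a median log2 fold change of -0.84 (camera adjusted p = 0.000291, or 0.846 with an estimated correlation). WRKY70, a transcription factor of the salicylic acid response, stood at 288 ± 123 CPM in early and 55.9 ± 14.0 CPM in late pools (log2 fold change -2.37 ± 0.44, edgeR adjusted p = 0.00600). The lectin gene LLP1 was also lower (log2 fold change -2.63 ± 0.52, edgeR adjusted p = 0.00752), and the member that was higher was AZI1. NLR genes encode intracellular immune receptors. They were lower in late pools, with 3 higher and 29 lower of 123 (4 and 30 over the list alone). Members had a median of -0.47 (camera adjusted p = 3.26e-05, or 0.891 with an estimated correlation). Members included AT1G63880 (-2.49 ± 0.35), AT1G59124 (-1.81 ± 0.27) and AT1G58807 (-1.82 ± 0.27). The last pair are near-identical, with uncertain counts. Several members are linked on chromosome 1 (below). Local alleles and mapping of Bur reads were not tested as causes. Cell division genes were lower, with 0 higher and 7 lower of 14 (0 and 7 over the list alone). The median was -1.24 (camera adjusted p = 1.15e-05, or 0.714 with an estimated correlation). The list included MCM2 (-2.09 ± 0.30), MCM7 (-1.94 ± 0.25) and MCM5 (-1.52 ± 0.23). Aliphatic glucosinolate genes were lower, with 0 higher and 5 lower of 22 (2 and 7 over the list alone). Their median was -0.71 (camera adjusted p = 0.00509, or 0.891 with an estimated correlation). Named members were FMOGS-OX3 (-2.28 ± 0.49), CYP79F1 (-2.22 ± 0.51) and UGT74C1 (-1.58 ± 0.34). Called genes named here had edgeR adjusted p of 0.00342 to 0.0120. The list calls ended without late_28d replicate 12 (0.199; median -0.38) for aliphatic glucosinolates and without late_28d replicate 11 (0.0629) for NLR genes. With all 24 libraries in 1 model, aliphatic glucosinolates (0.0786) and CYP79F1 (0.0765) were not called, nor were CYP79F1 (0.0563) and UGT74C1 (0.0519) with only the 6 libraries compared. Calls held while medians moved to -0.76 for NLR genes without late_28d replicate 12 and -0.28 for aliphatic glucosinolates without early_28d replicate 7.

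Jasmonate genes were higher in late pools at day 28, with 13 higher and 2 lower of 35 (15 and 4 over the list alone). For this list, the median log2 fold change was 0.50 (camera adjusted p = 0.0109, adjusted p = 0.714 with an estimated correlation). The regulator gene ORA59 (3.43 ± 0.60), the synthesis gene AOC1 (2.24 ± 0.33) and the repressor gene JAZ6 (1.86 ± 0.33) were higher. Leaf senescence genes were higher, with 6 higher and 1 lower of 28 (7 and 1 over the list alone). The list had a median log2 fold change of 0.55 (camera adjusted p = 0.0216, or 0.746 with an estimated correlation). They included SEN1 (3.99 ± 0.75), DIN10 (3.01 ± 0.73) and XTH24 (2.53 ± 0.57). Photosynthesis genes were higher, with 12 higher and 0 lower of 43 (16 and 0 over the list alone). A median log2 fold change of 0.28 was found (camera adjusted p = 0.00509, or 0.891 with an estimated correlation). Among them were PSBR (0.93 ± 0.20), LHCB1.2 (0.64 ± 0.13) and PSAL (0.63 ± 0.14). Of the floral regulators, SPL9 (-1.57 ± 0.43) and CDF1 (-1.40 ± 0.34) were lower in late pools and SPL4 was higher. Called genes of this paragraph had edgeR adjusted p of 0.00427 to 0.0326. Calls ended without early_28d replicate 8 (0.0524) for DIN10, early_28d replicate 8 (0.0527) for XTH24, early_28d replicate 7 (0.0533) for PSAL and early_28d replicate 7 (0.0653) for CDF1. That of SPL4 ended without early_28d replicates 7 (0.103), 8 (0.0941) and 9 (0.0570) and late_28d replicates 10 (0.0521) and 11 (0.0908). That of SPL9 ended without early_28d replicate 7 (0.107) and late_28d replicates 10 (0.0514) and 12 (0.0528). The list calls ended without late_28d replicate 10 (0.0776) for jasmonate, late_28d replicate 12 (0.114) for senescence and late_28d replicate 10 (0.216) for photosynthesis. With all 24 libraries in 1 model, jasmonate (0.0786), senescence (0.0786) and DIN10 (0.0680) and SPL9 (0.0630) were not called. With only the 6 libraries compared, DIN10 (0.0577), PSBR (0.0604), LHCB1.2 (0.0625), PSAL (0.0840), SPL9 (0.0558), CDF1 (0.0767) and SPL4 (0.0588) were not called.

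PR1 stood at a mean of 23.9 CPM in late pools (3.38 to 59.5) and 336 CPM in early pools (235 to 507) at day 28 and was not called (edgeR adjusted p = 0.0881, 0.0444 to 0.188 over its alternatives). It was called without late_28d replicate 12. PR2 (-0.59 ± 0.76), PR5 (-0.07 ± 0.73), ICS1 (-0.67 ± 0.44), SVP (-0.45 ± 0.23), MAF2 (0.35 ± 0.19) and FRI (0.10 ± 0.21) were not called either. SOC1, an activator of flowering, gave -0.59 ± 0.20 with an edgeR adjusted p = 0.0510 (0.0138 to 0.173 over its alternatives). It was called by DESeq2, with median-of-ratios factors, with all 24 libraries in 1 model and without late_28d replicate 10 or 11. FT (chromosome 1, 24331373 to 24333999) had 1 to 20 counts summed per group and was not tested, and SAG12, which has no line in the table, was not analysed here. The edgeR count was 1534 without early_28d replicate 7 and 1661 without early_28d replicate 8.

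The other gene groups at day 28 were not called by camera. Pattern-triggered immunity had 1 higher and 2 lower of 28 (0 and 0 over the list alone). Camalexin synthesis had 1 higher and 2 lower of 7 (2 and 2 over the list alone). Indole glucosinolates and myrosinases had 1 higher and 2 lower of 16 (1 and 1 over the list alone). Flavonoids and anthocyanins had 0 higher and 4 lower of 11 (0 and 4 over the list alone). Floral activators had 1 higher and 1 lower of 11 (1 and 3 over the list alone). Floral repressors had 1 higher and 1 lower of 17 (1 and 1 over the list alone). The circadian clock had 2 higher and 4 lower of 18 (4 and 4 over the list alone). Cold and abscisic acid response had 0 higher and 1 lower of 23 (0 and 1 over the list alone). Heat shock had 1 higher and 1 lower of 13 (1 and 1 over the list alone). Phosphate starvation had 2 higher and 0 lower of 6 (2 and 0 over the list alone). Ribosomal proteins had 18 higher and 20 lower of 307 (7 and 10 over the list alone). Stomatal lineage markers had 0 higher and 1 lower of 10 (0 and 1 over the list alone). Vascular markers had 0 higher and 1 lower of 9 (0 and 1 over the list alone). Markers of other organs were nearly absent, with 0 tested members for the shoot meristem, 2 for the flower and 2 for the root.

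**Figure D2:**
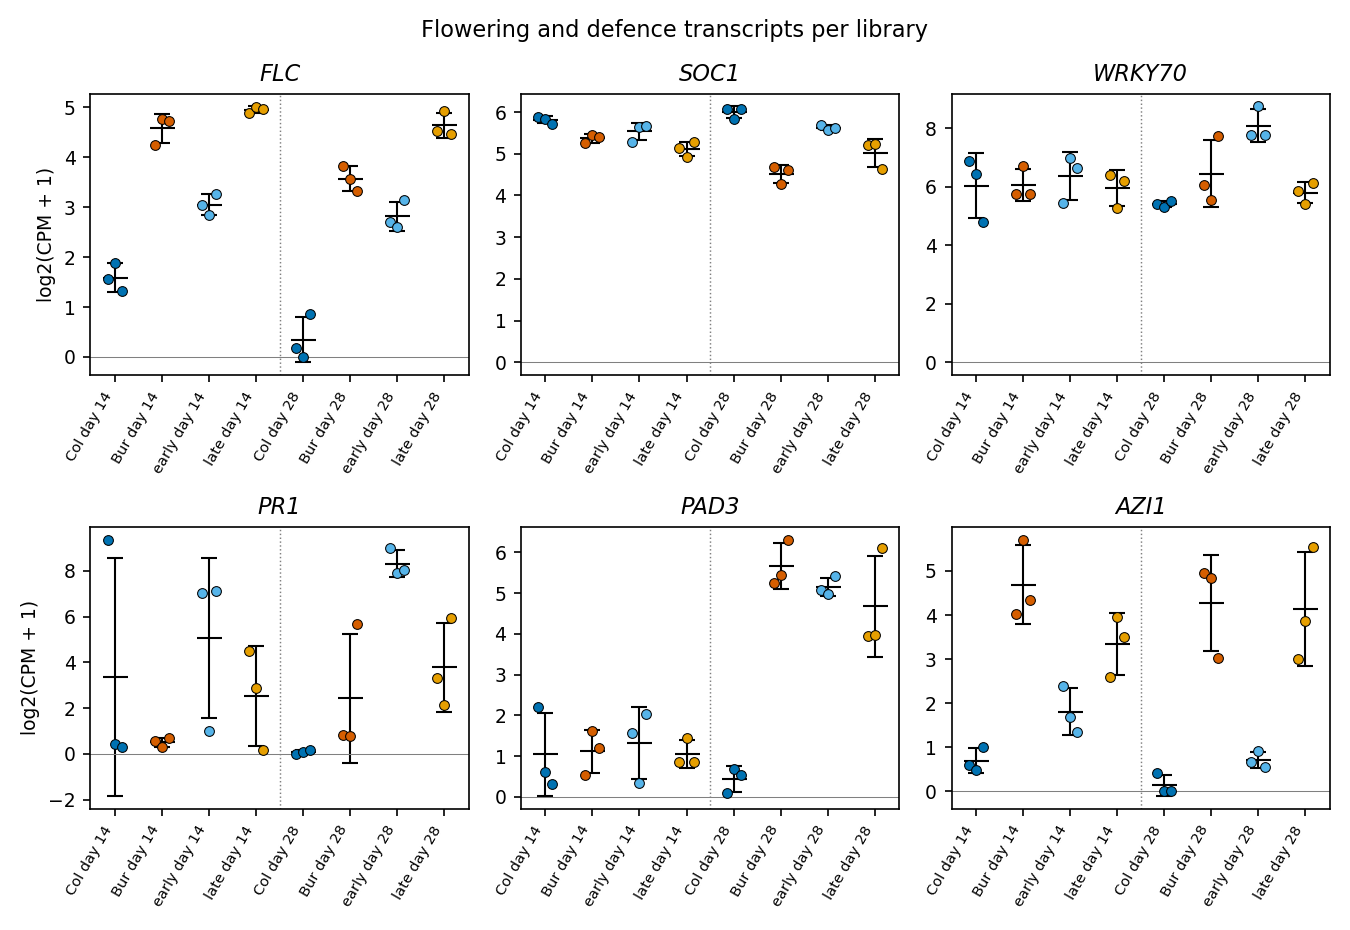
Values per library (points, log2(CPM + 1)) of FLC, SOC1, WRKY70, PR1, PAD3 and AZI1 in the 8 groups of 3 libraries, with bars at the group mean ± SD on that scale. WRKY70 has a mean of 288 CPM in early_28d and 55.9 CPM in late_28d, and PR1 varies from 0.239 to 653 CPM within Col_14d.

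**Figure D3:**
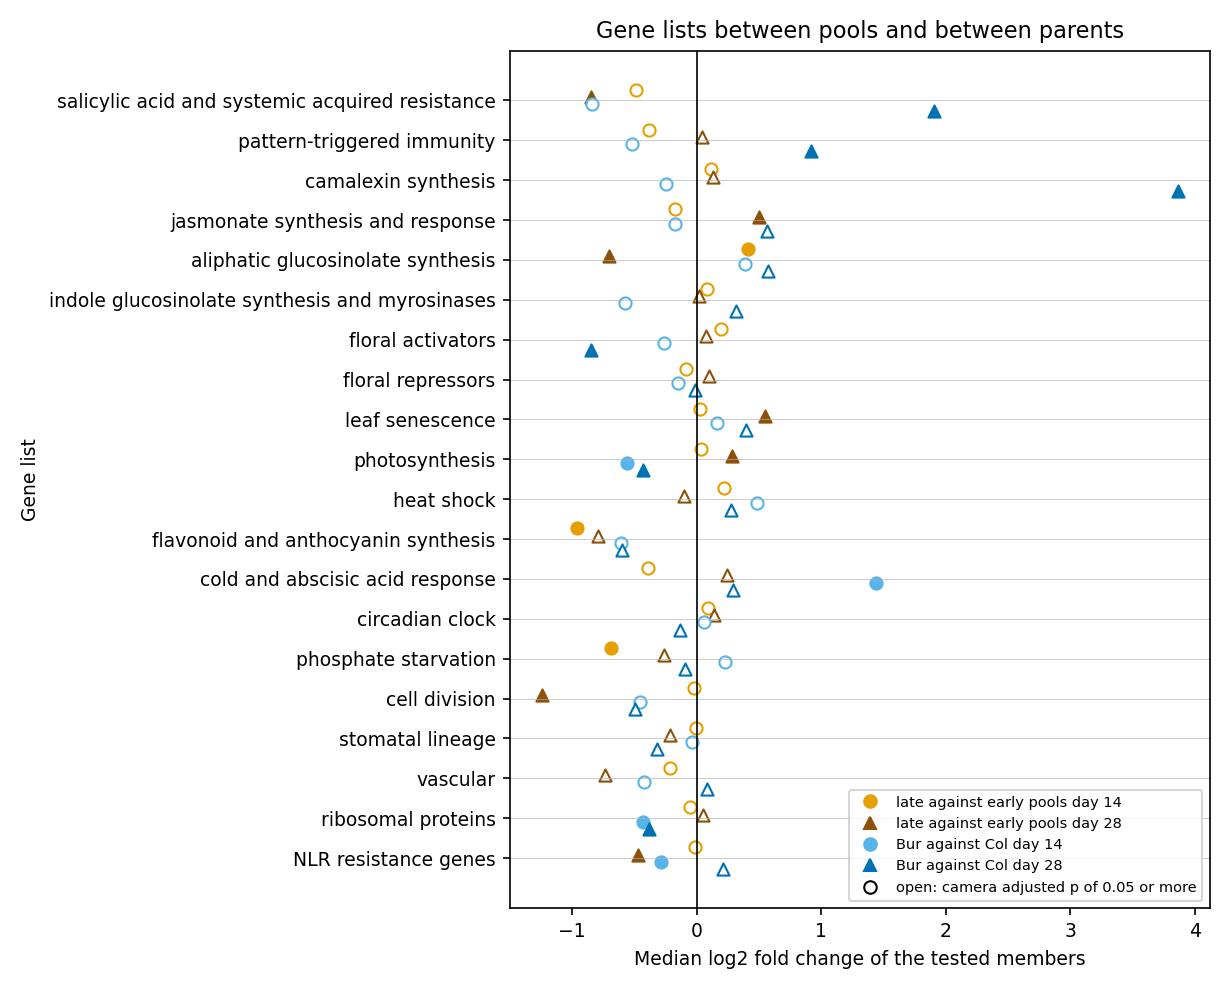
Median log2 fold change of each gene list (points) in the late against early and Bur against Col comparisons at both days, with open points at a camera adjusted p of 0.05 or more. The salicylic acid list lies at -0.84 in late against early pools and at 1.90 in Bur against Col at day 28.

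The comparison of Bur-0 with Col-0 asks which differences the parents could pass to the recombinant lines. At day 14, FLC was higher in Bur (23.3 ± 4.57 against 2.05 ± 0.606 CPM, log2 fold change 3.51 ± 0.52, edgeR adjusted p = 0.000732). Its relative MAF4 was lower (-3.47 ± 0.54), as was the floral activator SPL4 (-3.44 ± 0.36). The clock and photoperiod genes PRR3 (6.89 ± 0.49), FKF1 (5.30 ± 0.47) and GI (1.98 ± 0.34) were higher in Bur, while the clock list, with 8 higher and 6 lower of 19 (8 and 6 over the list alone), was not called (camera adjusted p = 0.571, adjusted p = 0.947 with an estimated correlation). Other genes of largest increase were AT5G24240 (8.06 ± 1.02), the non-coding RNA AT1G67105 (8.03 ± 0.96) and AT5G34965 (8.00 ± 0.99), AT5G15360 (7.10 ± 1.01) and RE2 (6.91 ± 0.51). AT5G15360 was 11.77 without Col_14d replicate 1. Genes of largest decrease lie close together on chromosome 1 and start between 8774997 and 8826983. They were AT1G25098 (-11.51 ± 0.49), AT1G24996 (-11.18 ± 0.42), AT1G25175 (-11.10 ± 0.53), AT1G24822 (-10.99 ± 0.39) and AT1G25097 (-10.99 ± 0.39), the last pair with identical counts. AT2G04378 had 1 count in Bur and 1573 in Col (ratio 1614, 95% interval 289 to 63777). From edgeR, adjusted p were 5.17e-08 to 0.00186 for the called genes of this paragraph. edgeR called 5496 of 18885 genes, 2607 higher and 2889 lower in Bur, of which 2766 differed by at least 2-fold. Of the called genes 399 differed by at least 16-fold (262 lower and 137 higher in Bur), and 434 at day 28 (225 lower and 209 higher). Poor matching of Bur reads to the reference was not tested for these.

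Cold and abscisic acid response genes were higher in Bur at day 14, with 13 higher and 0 lower of 23 (14 and 0 over the list alone). Tested members had a median log2 fold change of 1.44 (camera adjusted p = 4.27e-05, adjusted p = 0.947 with an estimated correlation). Members included CBF3 (3.92 ± 0.60), COR413IM1 (2.58 ± 0.43) and COR15B (2.29 ± 0.29). Photosynthesis genes were lower, with 0 higher and 28 lower of 43 (0 and 34 over the list alone). This gave a median log2 fold change of -0.56 (camera adjusted p = 5.13e-06, adjusted p = 0.947 with an estimated correlation). The list included FBA2 (-1.38 ± 0.20), GAPA1 (-1.31 ± 0.24) and PETE1 (-1.14 ± 0.17). Ribosomal protein genes were lower, with 16 higher and 122 lower of 307 (18 and 132 over the list alone). Across members, the median log2 fold change was -0.43 (camera adjusted p = 4.26e-05, adjusted p = 0.947 with an estimated correlation). The S5 genes AT1G58684, AT1G58983 and AT1G59359 were among them (-2.02 ± 0.17 for the pair with identical counts) and cannot be told from each other. NLR resistance genes differed in both directions, with 24 higher and 43 lower of 124 (28 and 46 over the list alone). As a group they had a median of -0.29 (camera adjusted p = 4.26e-05, adjusted p = 0.947 with an estimated correlation). Named members were AT4G19520 (-8.76 ± 0.47) and AT5G46510 (-6.35 ± 0.31). AT5G36930, of the same list, had 2 counts in Bur and 1019 in Col (ratio 523, 95% interval 144 to 4322). The called genes given here had edgeR adjusted p of 4.13e-07 to 0.00250. Medians moved while calls held, to 0.94 for cold response without Bur_14d replicate 2 and 2.24 for cold response without Col_14d replicate 3.

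Salicylic acid genes were not called between the parents at day 14, with 1 higher and 4 lower of 36 (1 and 1 over the list alone). The median log2 fold change was -0.84 (camera adjusted p = 0.571, adjusted p = 0.947 with an estimated correlation). In this list AZI1 was higher in Bur (log2 fold change 5.45 ± 0.80, edgeR adjusted p = 0.000735) and SARD4 was lower (log2 fold change -2.27 ± 0.48, edgeR adjusted p = 0.00574). PR1 had a mean of 0.429 CPM in Bur and stood at 218 ± 377 CPM in Col, with 0.239 to 653 CPM in single Col libraries. Its call (log2 fold change -8.98 ± 2.97, edgeR adjusted p = 0.0426) ended without Bur_14d replicates 1 (0.103), 2 (0.126) and 3 (0.115) and Col_14d replicate 1 (0.884; log2 fold change 0.56) and with the replicate block (0.220). PR2 (-3.16 ± 1.46) and PR5 (-3.01 ± 1.44) were not called. Without Col_14d replicate 1 the differences turned to higher in Bur for PR2 (2.25, edgeR adjusted p = 0.0162), PR5 (2.12, 0.0393) and the list median (0.32), which was -0.44 with the replicate block.

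At day 28, salicylic acid and systemic acquired resistance genes were higher in Bur than in Col, with 13 higher and 0 lower of 36 (20 and 0 over the list alone). For this list, the median log2 fold change was 1.90 (camera adjusted p = 0.000149, adjusted p = 0.874 with an estimated correlation). They included AZI1 (7.61 ± 1.01), WRKY54 (3.28 ± 0.78), PAD4 (2.03 ± 0.50) and ICS1 (1.00 ± 0.27). Camalexin is the main phytoalexin of Arabidopsis. Genes of its synthesis had 4 higher and 0 lower of 7 (4 and 0 over the list alone). The list had a median log2 fold change of 3.86 (camera adjusted p = 0.000765, adjusted p = 0.816 with an estimated correlation). Among them were PAD3 (7.07 ± 0.95), CYP71A13 (5.58 ± 0.61) and CYP71A12 (4.44 ± 0.59). Pattern-triggered immunity had 11 higher and 0 lower of 27 (12 and 0 over the list alone). A median log2 fold change of 0.92 was found (camera adjusted p = 0.00723, adjusted p = 0.874 with an estimated correlation). Members were NHL10 (3.51 ± 0.69), the flagellin receptor gene FLS2 (1.91 ± 0.34) and the MAP kinase gene MPK6 (0.48 ± 0.10). Across the called genes named here, edgeR adjusted p were 0.000134 to 0.0220. Calls ended without Col_28d replicate 1 (0.0505) for WRKY54, Col_28d replicate 1 (0.0591) for PAD4 and Bur_28d replicate 3 (0.0660) and Col_28d replicates 1 (0.0823) and 3 (0.0576) for ICS1. Without Bur_28d replicate 3, WRKY54 was 2.07 and PAD4 1.16, and AZI1 was 11.54 without Col_28d replicate 1. ICS1 also lost its call with all 24 libraries in 1 model (0.0639) and with the replicate block (0.0568). The call of pattern-triggered immunity ended without Bur_28d replicate 3 (0.0987; median 0.50). Medians moved, with calls kept, to 1.22 for salicylic acid without Bur_28d replicate 3.

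FLC stood at 0.313 CPM in Col at day 28 and was higher in Bur (log2 fold change 5.06 ± 0.63, edgeR adjusted p = 0.000319). Floral activators were lower in Bur, with 2 higher and 4 lower of 11 (2 and 4 over the list alone). Tested members had a median log2 fold change of -0.85 (camera adjusted p = 0.0287, adjusted p = 0.497 with an estimated correlation). Members included SPL4 (-3.34 ± 0.41), SPL5 (-2.45 ± 0.36) and SOC1 (-1.52 ± 0.14). The floral repressors MAF4 (-3.84 ± 0.53) and CDF1 (-1.78 ± 0.42) were lower too. Photosynthesis genes were lower, with 0 higher and 16 lower of 43 (0 and 29 over the list alone). This gave a median log2 fold change of -0.43 (camera adjusted p = 0.000149, adjusted p = 0.874 with an estimated correlation). The list included GAPA1 (-1.15 ± 0.24), CA1 (-0.89 ± 0.19) and PETE2 (-0.82 ± 0.18). Ribosomal protein genes were lower, with 10 higher and 93 lower of 307 (13 and 109 over the list alone). Across members, the median log2 fold change was -0.38 (camera adjusted p = 0.000149, adjusted p = 0.874 with an estimated correlation). Other genes of largest increase were AT1G67105 (9.54 ± 1.07), RE2 (9.46 ± 0.59), PCR1 (7.95 ± 1.82) and AT1G56120 (7.62 ± 1.16). AT2G43960 had 1 count in Col and 1800 in Bur (ratio 1677, 95% interval 301 to 66276). Called genes of this paragraph had edgeR adjusted p of 2.22e-06 to 0.0106. The F-box genes AT1G25211 (at least 946-fold lower), AT1G25150 (at least 982-fold lower), AT1G25055 (at least 991-fold lower), AT1G24800 (at least 994-fold lower) and AT1G24881 (at least 994-fold lower) had 0 counts in Bur, as had AT2G11240 (at least 1492-fold lower). These bounds are set against a floor of 3 counts over the group. PR1 had 3 counts in Col (0.0585 CPM) and was not called (edgeR adjusted p = 0.112), nor were PR2 (4.04 ± 1.53) and PR5 (2.78 ± 1.43). Both were called with only the 6 libraries compared, and PR2 with all 24 in 1 model. edgeR called 5059 of 18885 genes, 2474 higher and 2585 lower in Bur, of which 2709 differed by at least 2-fold. The count was 3372 without Bur_28d replicate 1, 2945 without Col_28d replicate 1 and 3208 without Col_28d replicate 3. With calls kept, medians moved to -1.33 for floral activators without Bur_28d replicate 3 and -1.35 for floral activators without Col_28d replicate 2.

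The clock genes plotted, and the sets of 6 morning and 6 evening genes, were chosen after their values were seen. The mean log2(CPM + 1) of the evening set minus that of the morning set differed by 4.48 and 1.73 for Bur against Col at days 14 and 28, and by 2.62 and 2.05 for late against early pools. Groups compared did not overlap, but each exact permutation p = 0.1 is the lowest 3 against 3 libraries can give.

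**Figure D4:**
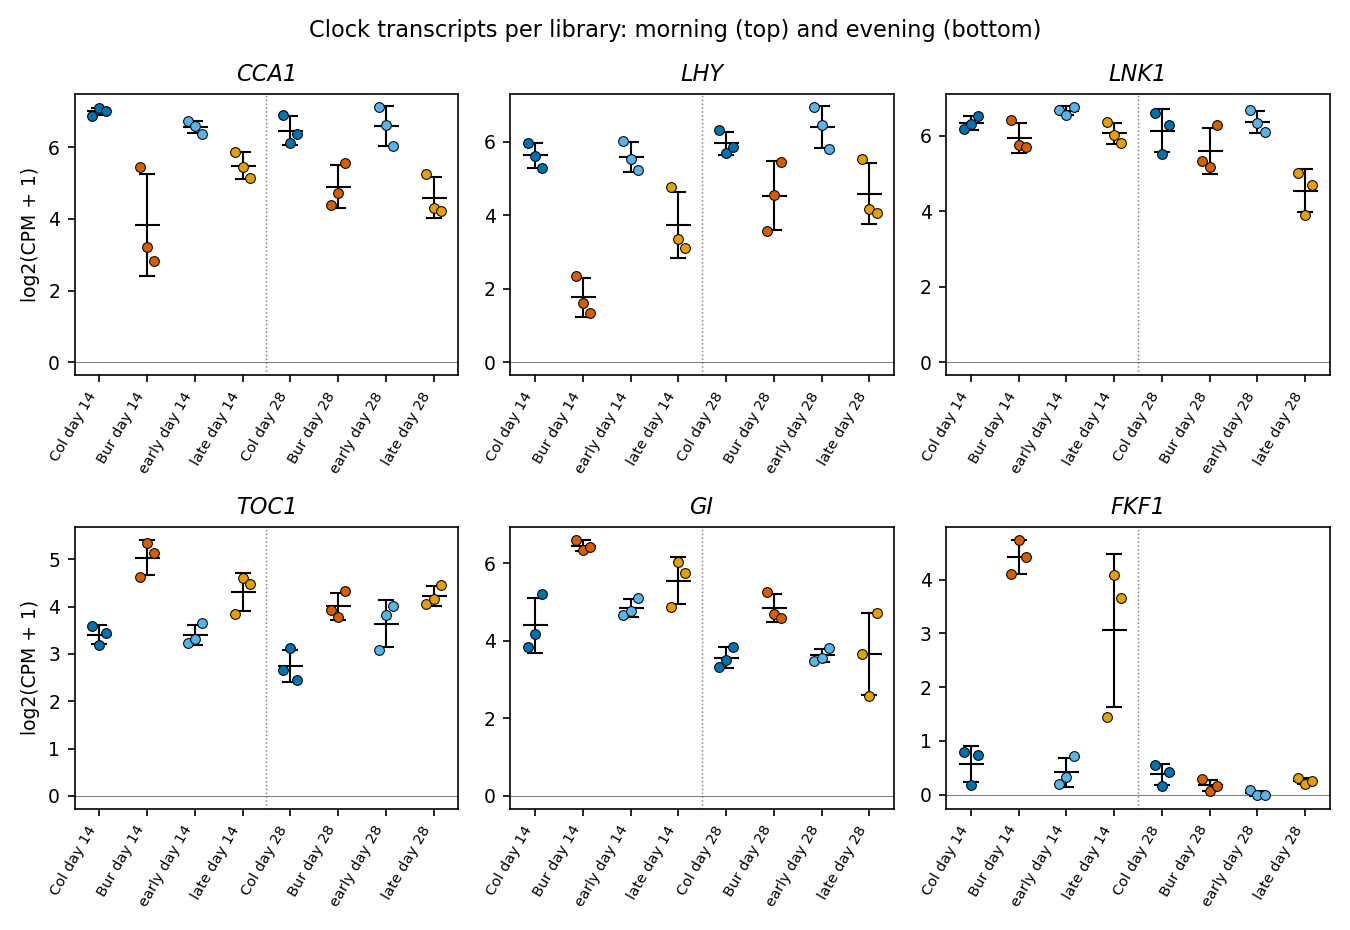
Values per library (points, log2(CPM + 1)) of the morning genes CCA1, LHY and LNK1 (top) and the evening genes TOC1, GI and FKF1 (bottom) in the 8 groups of 3 libraries, with bars at the group mean ± SD. CCA1 has a mean of 19.1 CPM in Bur_14d and 127 CPM in Col_14d.

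The change of the oldest leaf from day 14 to day 28 was compared within each material. In early pools, camalexin genes rose, with 4 higher and 0 lower of 7 (4 and 0 over the list alone). As a group they had a median of 1.73 (camera adjusted p = 4.99e-08, adjusted p = 0.0224 with an estimated correlation). Named members were CYP71A13 (5.60 ± 0.65) and CYP71A12 (5.17 ± 0.67). This was the 1 call among 78 over all comparisons that held with an estimated correlation. Salicylic acid genes had 13 higher and 0 lower of 40 (24 and 1 over the list alone). The median log2 fold change was 1.38 (camera adjusted p = 7.96e-19, adjusted p = 0.0977 with an estimated correlation). Pattern-triggered immunity had 3 higher and 0 lower of 28 (3 and 0 over the list alone). For this list, the median log2 fold change was 0.85 (camera adjusted p = 1.06e-05, adjusted p = 0.360 with an estimated correlation). A member was NHL10 (4.21 ± 0.69). AGL19 (3.92 ± 0.46) and AGL24 (2.89 ± 0.47), which promote flowering, rose, as did AT2G33850 (5.56 ± 0.82). The metal chelator gene NAS3 (-5.20 ± 0.54) and the glucosinolate gene MAM3 (-4.56 ± 0.49) fell. Aliphatic glucosinolate genes had 0 higher and 2 lower of 22 (0 and 4 over the list alone). The list had a median log2 fold change of -0.72 (camera adjusted p = 4.33e-08, adjusted p = 0.271 with an estimated correlation). Cold and abscisic acid response genes had 0 higher and 3 lower of 23 (0 and 11 over the list alone). A median log2 fold change of -0.94 was found (camera adjusted p = 2.94e-08, adjusted p = 0.187 with an estimated correlation). From edgeR, adjusted p were 0.00212 to 0.00985 for the called genes of this paragraph. edgeR called 635 genes, 280 higher and 355 lower at day 28. The count was 226 and 196 without early_14d replicates 2 and 3, 93 without early_28d replicate 8 and 250 without early_28d replicate 9. Of 30 genes that the rule named here, 10 kept their call without each library in turn, among them all genes given in this paragraph. camera also called floral activators, senescence, flavonoids, clock, phosphate starvation, cell division, stomatal lineage, ribosomal proteins and NLR genes, none of which held with an estimated correlation. The calls ended without early_14d replicates 1 (0.190; median 0.24) and 3 (0.0540) and early_28d replicates 8 (0.0716) and 9 (0.238; median 0.20) for senescence. For the clock they ended without early_14d replicates 1 (0.0566) and 3 (0.0584) and early_28d replicates 8 (0.0507; median -0.07) and 9 (0.111), and for NLR genes without early_28d replicates 8 (0.102; median 0.16) and 9 (0.303; median 0.08). With all 24 libraries in 1 model, those of senescence (0.102) and the clock (0.0601) ended, and that of the clock also without a filter on low counts (0.0574). Calls held while medians moved to 0.55 for pattern-triggered immunity without early_14d replicate 1 and 0.56 for pattern-triggered immunity without early_28d replicate 9.

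In late pools, aliphatic glucosinolate genes fell with age, with 0 higher and 19 lower of 22 (0 and 21 over the list alone). Tested members had a median log2 fold change of -2.04 (camera adjusted p = 3.37e-20, adjusted p = 0.177 with an estimated correlation). Among them were MAM3 (-3.36 ± 0.45) and SOT17 (-2.53 ± 0.37). Camalexin genes rose, with 4 higher and 0 lower of 7 (4 and 0 over the list alone). This gave a median of 2.44 (camera adjusted p = 0.00364, or 0.177 with an estimated correlation). Members included PAD3 (4.83 ± 0.78) and GSTF6 (2.44 ± 0.44). Pattern-triggered immunity had 6 higher and 0 lower of 28 (9 and 0 over the list alone). Members had a median of 1.02 (camera adjusted p = 9.18e-05, or 0.592 with an estimated correlation). A member was NHL10 (5.53 ± 0.76). Salicylic acid genes had 8 higher and 1 lower of 40 (8 and 1 over the list alone). As a group they had a median of 1.02 (camera adjusted p = 9.18e-05, or 0.554 with an estimated correlation). Named members were PNP-A (3.64 ± 0.74) and BAP1 (2.86 ± 0.54). Senescence genes had 7 higher and 1 lower of 28 (10 and 2 over the list alone). Their median was 0.81 (camera adjusted p = 0.000682, or 0.218 with an estimated correlation). They included SAG21 (3.73 ± 0.57) and ASN1 (3.28 ± 0.53). Clock genes had 1 higher and 8 lower of 18 (1 and 9 over the list alone). For this list the median was -0.64 (camera adjusted p = 0.00437, or 0.177 with an estimated correlation). Among them were PRR5 (-4.04 ± 0.71) and LNK1 (-1.51 ± 0.28). Cold response genes had 1 higher and 4 lower of 23 (1 and 7 over the list alone). The list had a median of -0.83 (camera adjusted p = 0.00605, or 0.592 with an estimated correlation). Members included CBF3 (-3.83 ± 0.69) and RD29A (-3.45 ± 0.46). GDPD2 (5.04 ± 0.87), ERD5 (4.78 ± 0.58) and GAD4 (4.45 ± 0.89) also rose. LTP3 (-5.86 ± 1.11), AT5G23240 (-4.99 ± 0.61), AT5G47330 (-4.43 ± 0.74) and NAS3 (-4.39 ± 0.50) fell. The called genes given here had edgeR adjusted p of 0.00144 to 0.00883. edgeR called 3036 genes, 1497 higher and 1539 lower at day 28. The count was 1580, 1302 and 1474 without late_14d replicates 4, 5 and 6. camera also called jasmonate, photosynthesis and ribosomal protein genes, none of which held with an estimated correlation. The calls ended without late_28d replicate 10 (0.110) for jasmonate and without late_14d replicates 4 (0.0506) and 5 (0.115) and late_28d replicate 10 (0.561; median 0.05) for photosynthesis. Medians moved while calls held, to 0.51 for salicylic acid without late_28d replicate 12 and -0.42 for the clock without a filter on low counts.

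In Bur, camalexin genes rose with leaf age, with 4 higher and 0 lower of 7 (4 and 0 over the list alone). A median log2 fold change of 1.58 was found (camera adjusted p = 5.30e-05, adjusted p = 0.205 with an estimated correlation). The list included CYP71A13 (5.38 ± 0.59), PAD3 (5.36 ± 0.83) and CYP71A12 (3.86 ± 0.56). Salicylic acid genes had 6 higher and 0 lower of 36 (10 and 0 over the list alone). Tested members had a median log2 fold change of 1.52 (camera adjusted p = 6.87e-06, adjusted p = 0.487 with an estimated correlation). Named members were EDS5 (2.12 ± 0.42) and ICS1 (1.67 ± 0.28). Pattern-triggered immunity had 9 higher and 0 lower of 27 (14 and 0 over the list alone). This gave a median log2 fold change of 1.05 (camera adjusted p = 6.87e-06, adjusted p = 0.316 with an estimated correlation). A member was NHL10 (4.06 ± 0.73). Indole glucosinolate and myrosinase genes had 5 higher and 1 lower of 16 (9 and 3 over the list alone). Across members, the median log2 fold change was 1.12 (camera adjusted p = 0.00164, adjusted p = 0.205 with an estimated correlation). Among them were TGG2 (1.97 ± 0.22) and TGG1 (1.63 ± 0.19). Cold response genes had 0 higher and 10 lower of 23 (0 and 15 over the list alone). As a group they had a median of -1.58 (camera adjusted p = 8.04e-08, adjusted p = 0.205 with an estimated correlation). Members included CBF3 (-4.06 ± 0.60) and COR15B (-2.53 ± 0.30). Clock genes had 2 higher and 7 lower of 19 (2 and 9 over the list alone). The median log2 fold change was -0.54 (camera adjusted p = 0.00139, adjusted p = 0.112 with an estimated correlation). The list included PRR3 (-5.56 ± 0.43) and ELF4 (-4.49 ± 0.52). FKF1 (-7.25 ± 0.56), LTP3 (-6.60 ± 0.80) and NAS3 (-5.66 ± 0.65) fell most, while LTL1 (6.29 ± 0.57) and AT1G26380 (5.89 ± 0.79) rose. AT2G33850 had 3 counts at day 14 and 1264 at day 28 (ratio 405, 95% interval 138 to 1969). SVP (-1.27 ± 0.16), TOE2 (-1.16 ± 0.24) and SOC1 (-0.87 ± 0.14) fell. FLC (-1.08 ± 0.46) was not called (edgeR adjusted p = 0.126, 0.0333 to 0.269 over its alternatives), but was by DESeq2, with only the 6 libraries compared and with all 24 in 1 model. Across the called genes named here, edgeR adjusted p were 0.000110 to 0.0115. edgeR called 3050 genes, 1399 higher and 1651 lower at day 28. The count was 1364 and 1569 without Bur_14d replicates 2 and 3. camera also called floral repressors, photosynthesis, cell division, stomatal lineage, vascular and ribosomal protein genes, none of which held with an estimated correlation. The calls ended without Bur_28d replicate 2 (0.0616) for floral repressors and without Bur_14d replicate 2 (0.534; median 0.06) and Bur_28d replicate 2 (0.450; median 0.09) for photosynthesis. With the replicate block, photosynthesis (0.0688) was not called, nor was EDS5 (0.0544) with only the 6 libraries compared. Medians moved, with calls kept, to 0.60 for salicylic acid, 0.57 for pattern-triggered immunity and 0.51 for indole glucosinolates without Bur_28d replicate 3 and -0.25 for the clock without Bur_14d replicate 1.

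In Col, floral activators rose with leaf age, with 5 higher and 1 lower of 11 (5 and 2 over the list alone). For this list, the median log2 fold change was 1.21 (camera adjusted p = 0.00405, adjusted p = 0.110 with an estimated correlation). Named members were AGL19 (3.10 ± 0.31) and AGL24 (2.78 ± 0.37). Floral repressors fell, with 0 higher and 4 lower of 16 (0 and 6 over the list alone). The list had a median log2 fold change of -0.45 (camera adjusted p = 0.00405, adjusted p = 0.110 with an estimated correlation). They included FLC (-2.64 ± 0.65) and TOE2 (-2.06 ± 0.25). Cell division genes had 6 higher and 0 lower of 14 (8 and 0 over the list alone). A median log2 fold change of 0.87 was found (camera adjusted p = 5.08e-08, adjusted p = 0.123 with an estimated correlation). A member was MCM5 (1.40 ± 0.17). Heat shock genes had 4 higher and 0 lower of 13 (5 and 0 over the list alone). Tested members had a median log2 fold change of 0.50 (camera adjusted p = 0.00277, adjusted p = 0.123 with an estimated correlation). Members included HSFA2 (3.61 ± 0.65) and HSP17.4B (2.27 ± 0.44). Salicylic acid genes had 0 higher and 3 lower of 36 (0 and 0 over the list alone). This gave a median log2 fold change of -0.91 (camera adjusted p = 0.0398, adjusted p = 0.822 with an estimated correlation). PR2 was called lower (-5.90 ± 1.67), which rests on Col_14d replicate 1. PR1 was not called (edgeR adjusted p = 0.0540, 0.0245 to 0.748 over its alternatives), but was without Col_14d replicate 2 or 3 and with all 24 libraries in 1 model. The wax synthesis gene KCS16 rose (3.82 ± 0.30), as did PDF1 (4.22 ± 0.61), and NAS3 fell (-5.94 ± 0.69). Called genes of this paragraph had edgeR adjusted p of 0.000171 to 0.0402. edgeR called 2553 genes, 1139 higher and 1414 lower at day 28. The count was 1106 and 1529 without Col_14d replicates 1 and 2, and 1099 and 1032 without Col_28d replicates 1 and 3. The call of PR2 ended without Col_14d replicate 1 (0.628; log2 fold change -0.49) and Col_28d replicates 1 (0.130), 2 (0.0997) and 3 (0.119) and that of FLC without Col_14d replicates 1 (0.0649) and 2 (0.0711) and Col_28d replicate 1 (0.0913). With only the 6 libraries compared, FLC (0.0727) and PR2 (0.0879) were not called, nor were FLC (0.0921) and PR2 (0.472) with the replicate block. FLC was -4.86 without Col_28d replicate 3. The salicylic acid list lost its call without Col_14d replicate 1 (0.799; median -0.41) and Col_28d replicate 1 (0.0833). camera also called stomatal lineage, clock and ribosomal protein genes, none of which held with an estimated correlation. With calls kept, medians moved to 0.71 for floral activators without a filter on low counts, -0.26 for floral repressors without Col_14d replicate 1 and -0.57 for salicylic acid with the replicate block.

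Whether the differences changed between the days was tested by interaction. KCS16 had a Bur against Col difference of 3.15 at day 14 and -0.52 at day 28. The change of -3.66 ± 0.39 (edgeR adjusted p = 0.00920) held without each library in turn. For the parents edgeR called 297 genes, 146 with a higher and 151 with a lower difference at day 28. The count was 176, 62 and 18 without Bur_14d replicates 1, 2 and 3, and 50 without Bur_28d replicate 1. It was 36 and 50 without Col_14d replicates 1 and 2, and 9, 639 and 3 without Col_28d replicates 1, 2 and 3. For late against early pools edgeR called 0 genes, with a smallest adjusted p = 0.158, 2254 genes at an unadjusted p under 0.05, and 203 genes by DESeq2. The 5 and 4219 genes called at days 14 and 28 were thus not shown to differ gene by gene between the days.

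Transcripts that differed between the pools at day 28 tended to differ the same way between the parents, whose libraries are separate. FLC and AZI1 were higher both in late pools and in Bur. Of 18552 genes tested in both, 580 were higher both in late pools and in Bur, against 283 expected (1-sided Fisher exact adjusted p = 2.36e-74). Lower in both were 544, against 275 expected (adjusted p = 6.07e-64). Higher in late pools and lower in Bur were 114 against 296 expected, and the reverse 43 against 263. At day 14 the 3 genes lower in late pools were all lower in Bur, against 0.456 expected (Fisher exact adjusted p = 0.00937), and of the 2 higher genes 1 was higher and 1 lower in Bur (adjusted p = 0.450 each), with adjustment over 8 overlaps. The log2 fold changes correlated across genes with r = 0.226 and rho = 0.148 at day 14, and r = 0.257 and rho = 0.342 at day 28. Genes are not independent replicates, so these p-values overstate the evidence. The same-direction count of 1124 was 452 and 466 without early_28d replicates 7 and 8, and 708 without Bur_28d replicate 1. It was 635 and 700 without Col_28d replicates 1 and 3.

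The called genes were then placed on the genome, since lines chosen for flowering time can differ in parental alleles around the loci that control it. At day 28, 1 of 112 windows of 1 Mb held more called genes than the rest, at 27 to 28 Mb of chromosome 1. It had 72 of 219 tested genes (32.9%, against 22.5% of all genes; 30 higher and 42 lower; 1-sided Fisher exact adjusted p = 0.0304). It holds JAZ6, higher in late pools, and SARD1, a regulator of salicylic acid synthesis, which was lower (-1.41 ± 0.46). The NLR genes AT1G72840 (-2.46 ± 0.40), AT1G72850 (-2.16 ± 0.60), AT1G72860 (-1.61 ± 0.36) and AT1G72890 (-1.29 ± 0.35) were also lower there. The next smallest p were at 15 to 16 Mb of chromosome 2, 21 to 22 Mb of chromosome 1, 5 to 6 Mb of chromosome 5 and 2 to 3 Mb of chromosome 2, none of them called. The window at 21 to 22 Mb of chromosome 1 holds the NLR genes AT1G58602 (-1.94 ± 0.34) and AT1G59218 (-2.09 ± 0.33). At day 14 Fisher's exact test called 0 of 112 windows. Those at 23 to 24 Mb of chromosome 1, with AT1G63880 and BETA-VPE, and at 3 to 4 Mb of chromosome 5, with FLC and AT5G11580, had an adjusted p = 0.0673. Linked genes are not independent, and without late_28d replicate 10 or replicate 12 the day 28 count of windows was 0.

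Within windows of 2 Mb, the late against early difference was set against the Bur against Col difference of genes that differ at least 2-fold between the parents. The slope is positive where late pools resemble Bur. In the window of FT (24 to 26 Mb of chromosome 1) it was 0.356 ± 0.034 at day 14 and 0.345 ± 0.035 at day 28. The window of FRI, an activator of FLC at 0 to 2 Mb of chromosome 4, had 0.130 ± 0.026 and 0.199 ± 0.037. The window of SOC1 had 0.0776 and 0.161, that of SVP 0.0373 and 0.0920, and that of MAF2 0.20 and 0.226. The window of FLC itself (2 to 4 Mb of chromosome 5) had -0.0867 ± 0.049 and -0.0388 ± 0.064. The highest slopes were 0.405 at 22 to 24 Mb of chromosome 1 at day 14 and 0.354 at 28 to 30 Mb of the same chromosome at day 28. Over 58 windows at day 14 and 59 at day 28, the median slope was 0.123 and 0.131. By more than 2 SE, 36 and 37 windows lay above 0 and 9 and 3 below. Slopes of both days correlated across 57 windows with r = 0.863 and rho = 0.842 (permutation p = 1e-05, the smallest that 100000 permutations can give). Without the 2 windows farthest from the median r was 0.855. Neighbouring windows share linked alleles and are not independent.

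**Figure D5:**
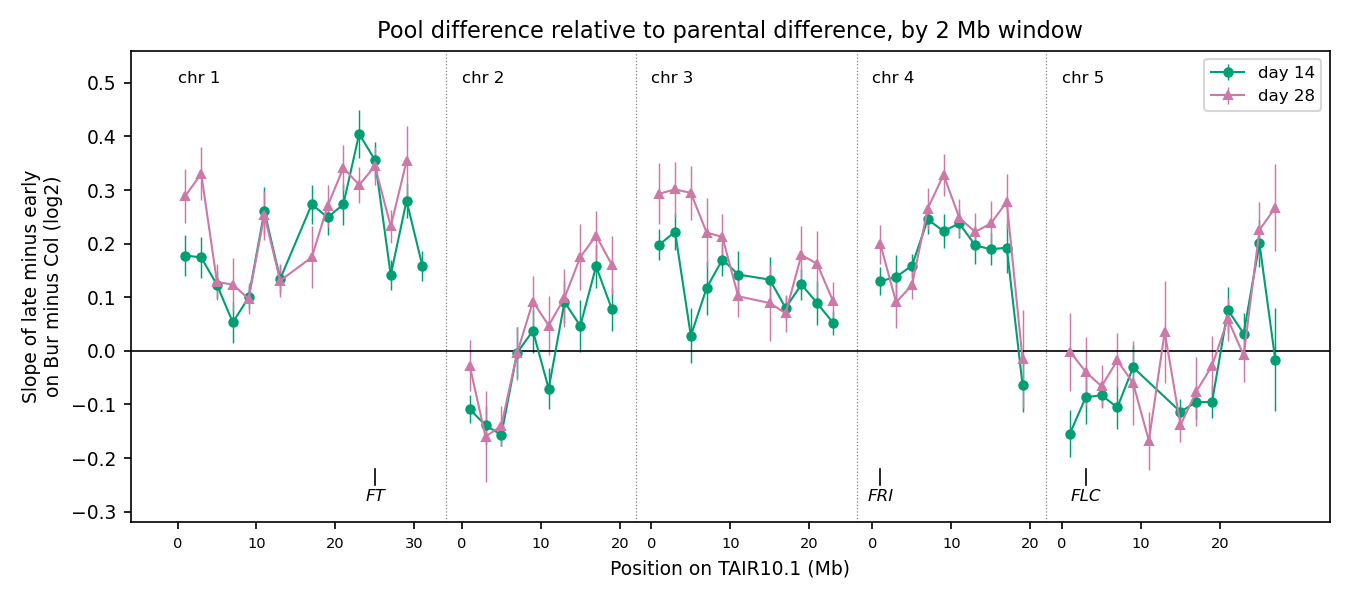
Slope of the late against early on the Bur against Col log2 fold change (vertical axis, no unit, bars ± SE) per 2 Mb window along the 5 chromosomes (horizontal axis, Mb), with 1 line for each day joining the windows measured. Slopes run from -0.157 to 0.405 at day 14 and from -0.168 to 0.354 at day 28, and the window of FT lies at 0.356 and 0.345.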

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

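The tests of the spread of slopes, and of slopes between the days were chosen after the result was seen. The results that follow differ between the days by the test of the interaction. The difference between Bur and Col in log2 fold change moved from day 14 to day 28 for several genes, given with the edgeR adjusted p of the change and the differences at both days in brackets. It moved up for the camalexin genes PAD3 by 7.31 ± 1.25 (0.0275; -0.24 to 7.07) and CYP71A13 by 6.89 ± 0.90 (0.0147; -1.31 to 5.58). It also moved up for PP2-B14 by 6.92 ± 1.29 (0.0341; -3.58 to 3.34), SAL2 by 5.91 ± 1.11 (0.0345; -1.11 to 4.80) and AT1G26380 by 5.79 ± 1.02 (0.0315; -1.88 to 3.91). It moved down for the wax and fatty acid genes CER1 by -4.77 ± 0.58 (0.0114; 1.49 to -3.28), FAR1 by -4.09 ± 0.76 (0.0341; 2.98 to -1.11), KCS16 by -3.66 ± 0.39 (0.00920; 3.15 to -0.52) and KCS8 by -3.28 ± 0.55 (0.0272; 2.08 to -1.20) and for the cold genes CBF1 by -4.56 ± 0.83 (0.0329; 3.40 to -1.16) and COR15B by -2.13 ± 0.40 (0.0354; 2.29 to 0.16). The phloem genes moved as APL by 1.79 ± 0.29 (0.0261; -1.63 to 0.16) and SEOR1 by 0.96 ± 0.20 (0.0410; -0.63 to 0.33). Each of these calls but that of KCS16 ended without at least 1 library. CER1 lost its call without Col_28d replicate 3 (0.0513) and CYP71A13 without Bur_14d replicate 3 (0.0526) and Col_28d replicates 1 (0.0522) and 3 (0.0625), with the edgeR adjusted p in brackets here and below.

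PAD3 lost its call without Bur_14d replicates 2 (0.0520) and 3 (0.0822), Bur_28d replicate 1 (0.0577), Col_14d replicate 1 (0.0982) and Col_28d replicates 1 (0.0789) and 3 (0.0934). The call of PP2-B14 ended without Bur_14d replicates 1 (0.0545), 2 (0.0863) and 3 (0.101), Bur_28d replicate 1 (0.0612), Col_14d replicates 1 (0.0894) and 2 (0.0690) and Col_28d replicates 1 (0.0967) and 3 (0.0999). Without Bur_14d replicates 1 (0.0606), 2 (0.0767) and 3 (0.0969), Bur_28d replicate 1 (0.0692) and Col_28d replicates 1 (0.0967) and 3 (0.104), SAL2 was not called. AT1G26380 lost its call without Bur_14d replicates 1 (0.0555), 2 (0.0731) and 3 (0.0902), Bur_28d replicate 1 (0.0536), Col_14d replicates 1 (0.0772) and 2 (0.0685) and Col_28d replicates 1 (0.0789) and 3 (0.0987). The call of FAR1 ended without Bur_14d replicate 3 (0.0787), Bur_28d replicate 1 (0.0812), Col_14d replicates 1 (0.0972) and 2 (0.0698) and Col_28d replicates 1 (0.0903) and 3 (0.0878). Without Bur_14d replicate 3 (0.0673), Col_14d replicates 1 (0.0683) and 2 (0.0606) and Col_28d replicates 1 (0.0789) and 3 (0.0783), KCS8 was not called. CBF1 lost its call without Bur_14d replicates 2 (0.0726) and 3 (0.0858), Col_14d replicates 1 (0.0917) and 2 (0.0690) and Col_28d replicates 1 (0.0876) and 3 (0.0987). The call of COR15B ended without Bur_14d replicates 2 (0.0636) and 3 (0.0703), Bur_28d replicates 1 (0.0757) and 2 (0.0525), Col_14d replicates 1 (0.0917) and 2 (0.0690) and Col_28d replicates 1 (0.0870) and 3 (0.104). Without Bur_14d replicates 2 (0.0623) and 3 (0.0703), Bur_28d replicate 1 (0.0639), Col_14d replicates 1 (0.0683) and 2 (0.0601) and Col_28d replicates 1 (0.0722) and 3 (0.0878), APL was not called. SEOR1 lost its call without Bur_14d replicates 1 (0.0628), 2 (0.0987) and 3 (0.101), Bur_28d replicates 1 (0.0893) and 2 (0.0731), Col_14d replicates 2 (0.0780) and 3 (0.0526) and Col_28d replicates 1 (0.0996) and 3 (0.132). With the replicate block, PAD3 (0.111), PP2-B14 (0.0630), SAL2 (0.113), AT1G26380 (0.0833), FAR1 (0.0907), CBF1 (0.0872), COR15B (0.0686), APL (0.0975) and SEOR1 (0.124) were not called, nor were PP2-B14 (0.0579) and SEOR1 (0.139) with all 24 libraries in 1 model, or SEOR1 without a filter on low counts (0.0503).

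As groups, genes of 8 lists changed their late against early difference from day 14 to day 28 by camera, while edgeR called 0 single genes (2254 at an unadjusted p under 0.05, 203 by DESeq2). Cell division moved by a median of -1.14 (camera adjusted p = 2.19e-08, adjusted p = 0.366 with an estimated correlation). Aliphatic glucosinolates moved by a median of -1.12 (camera adjusted p = 1.50e-09, adjusted p = 0.375 with an estimated correlation). Salicylic acid moved by a median of -0.53 (camera adjusted p = 0.00619, adjusted p = 0.651 with an estimated correlation). NLR genes moved by a median of -0.39 (camera adjusted p = 7.28e-05, adjusted p = 0.779 with an estimated correlation). Phosphate starvation moved by a median of 0.60 (camera adjusted p = 0.0443, adjusted p = 0.375 with an estimated correlation). Jasmonate moved by a median of 0.52 (camera adjusted p = 1.56e-06, adjusted p = 0.146 with an estimated correlation). Senescence moved by a median of 0.48 (camera adjusted p = 0.0222, adjusted p = 0.375 with an estimated correlation). Photosynthesis moved by a median of 0.30 (camera adjusted p = 7.28e-05, adjusted p = 0.611 with an estimated correlation). The calls ended, with the camera adjusted p in brackets, without early_14d replicate 2 (0.138), late_14d replicate 4 (0.101; median -0.04), early_28d replicate 9 (0.0543) and late_28d replicate 11 (0.219) for salicylic acid, early_28d replicate 7 (0.0522) and late_28d replicate 12 (0.112) for senescence, early_14d replicate 1 (0.213; median 0.29), late_14d replicates 4 (0.0662) and 6 (0.0712), early_28d replicates 8 (0.0833; median 0.32) and 9 (0.0542) and late_28d replicates 10 (0.0798) and 12 (0.112) for phosphate starvation and late_28d replicate 11 (0.291; median -0.13) for NLR genes. With all 24 libraries in 1 model, salicylic acid (0.0930), senescence (0.0614) and phosphate starvation (0.0930) were not called. Calls held while medians moved to -0.35 for salicylic acid without early_14d replicate 1, -0.25 for NLR genes without early_28d replicate 9, -0.67 for NLR genes without late_28d replicate 12 and 0.17 for photosynthesis without late_28d replicate 10.

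In the parents, 6 lists changed their Bur against Col difference from day 14 to day 28. Salicylic acid moved by a median of 2.49 (camera adjusted p = 3.15e-11, or 0.474 with an estimated correlation). Camalexin moved by a median of 2.36 (camera adjusted p = 1.24e-06, or 0.400 with an estimated correlation). Pattern-triggered immunity moved by a median of 1.43 (camera adjusted p = 4.68e-07, or 0.474 with an estimated correlation). NLR genes moved by a median of 0.51 (camera adjusted p = 0.00141, or 0.696 with an estimated correlation). Vascular markers moved by a median of 0.46 (camera adjusted p = 0.0161, or 0.528 with an estimated correlation). Cold response moved by a median of -1.11 (camera adjusted p = 6.55e-06, or 0.474 with an estimated correlation). The calls ended, with the camera adjusted p in brackets, without Bur_14d replicate 2 (0.148; median 0.24), Col_14d replicates 2 (0.0506) and 3 (0.127; median 0.30) and Col_28d replicate 2 (0.0626) for vascular markers and Bur_28d replicate 3 (0.179; median 0.16) for NLR genes, and with the replicate block (0.0724) for vascular markers. Medians moved while calls held, to 0.73 for pattern-triggered immunity without Bur_28d replicate 3 and -0.64 for cold response without Bur_14d replicate 2.

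Slopes of the pool difference on the parental difference varied along the genome. A leaf-state change acting on genes anywhere would give slopes as even as shuffled ones, unless neighbours change together. The day 28 SD was 0.143, in shuffles at most 0.124. Single-library noise is argued against by r = 0.863 between days that share no library. The days must share lines, so this is not an independent repeat of the slopes. Different shares of parental alleles in late and early pools remain a candidate explanation, since the Bur share read from 97 genes near absent in 1 parent followed the slopes of other genes across 44 windows with r = 0.578 at day 28 (rho = 0.623, permutation p = 5e-05, r = 0.540 without the 2 farthest windows) and r = 0.848 at day 14 (rho = 0.859, permutation p = 1e-05, the smallest possible, r = 0.842 without the 2 farthest). Of 194 shares at each day, 6 at day 14 and 10 at day 28 lay outside 0 to 1 (lowest -0.460 and -2.04, highest 1.27 and 2.54), so that expression changes of these genes enter the measure. Both measures come from the same pool libraries and windows are linked, so this may overstate the relation.

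More genes were called between the pools at day 28 (4219) than at day 14 (5). The library that stood apart, late_28d replicate 11, is argued against as the cause, since 3940 genes were called at day 28 with it left out of the shared fit. This raised the day 14 count only to 35. Spread shared between the days may widen the gap but is not its sole cause. Each day's 6 libraries alone gave 1063 calls at day 28 and 12 at day 14. The variance of log2 fold changes beyond their standard errors was 3.17 times as large at day 28 (SD 0.699 against 0.392), so that larger differences between the pools at the later age may account for the counts. Whether these come from flowering, ageing or the choice of lines was not tested.

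The clock sets were chosen after values were seen. The clock list, not called between pools or parents, mixes morning and evening genes, whose opposite changes can cancel in camera. Within groups of the 24 libraries, the sets correlated with r = -0.676 (permutation p = 8e-05). The hour of harvest (not in labels), parents' clocks and mapping of Bur reads were not tested, also for changes shared by pools and parents.

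For each of the 8 comparisons of 2 groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 5, 4219, 5496, 5059, 635, 3036, 3050 and 2553 in the order of late against early pools and Bur against Col at days 14 and 28, and ageing in early pools, late pools, Bur and Col. The highest of the other splits was 45 for Bur against Col at day 28 and 0 for the rest. For the change of the parental difference between days, 1 of 50 splits gave as many as 297 genes, the highest other giving 35. The other splits mix Bur and Col libraries, which can widen the spread in their fits, so that they do not exclude chance. Leaving out single libraries moved this count from 3 to 639, so that it rests on few libraries. For the change of the pool difference, 50 of 50 splits gave at least the real 0, as any split must. Of the other splits 1 gave 312 genes, which may reflect a structure of the samples, and the rest gave 0.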

How the results depend on the processing

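The settings with late_28d replicate 11 left out of the shared fit and with genes of identical counts entered singly were chosen after seeing the data. Of 2805 alternatives of 234 called named genes, 2498 kept direction and call, 306 lost the call and 1 reversed, and 230 of 230 held with DESeq2 and 234 of 234 with median-of-ratios factors. Of 668 alternatives of 58 genes not called, 636 stayed so, 30 gained a call and 2 reversed. Of 1001 alternatives of the gene lists, 859 were the same, 139 weaker and 3 stronger. DESeq2 called 371 genes for late against early pools at day 14, 1482 for ageing early pools, 203 for the pool and 1540 for the parental change between days. With only the 6 libraries compared, counts were 12 and 1063 for the pools at days 14 and 28, 1474 for ageing late pools and 1462 for ageing Bur, with fewer samples to estimate the spread. With all 24 libraries in 1 model, counts were 113 for the pools at day 14, 979 for ageing early pools and 14 for the pool change between days, and 0 enriched windows. With late_28d replicate 11 left out of the shared fit, counts were 35 at day 14 and 1346 for ageing early pools. With the replicate block, counts were 1147 for ageing Bur, 965 for ageing Col and 20 for the parental change between days. The numbers do not pair the parents' libraries, since r by number ran from -0.31 to 0.43 and the own number was best for 4 of 12 pairs.

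Leaving out each library in turn gave 0 to 9 genes and 1534 to 5214 for the pools, 3678 to 5267 and 2945 to 4863 for the parents at days 14 and 28, 93 to 631, 1302 to 3503, 1364 to 2673 and 1032 to 2692 for ageing in early pools, late pools, Bur and Col, and 0 to 1 and 3 to 639 for the changes between days. Calls of lists numbered 78, 1 with an estimated correlation, and 74 to 84 leaving out each library. The salicylic acid list had medians of -0.49 (-0.76 to -0.26) and -0.84 (-1.10 to -0.76) in the pools and -0.84 (-1.09 to 0.32) and 1.90 (1.22 to 2.34) in the parents at days 14 and 28. Without a filter on low counts it was called at day 14 in the pools (-0.49, adjusted p = 0.0484, 9.82e-06 to 0.825 over its alternatives), and with an estimated correlation the day 28 medians of -0.84 and 1.90 had adjusted p = 0.846 and 0.874. The r of pool and parental changes was 0.198 to 0.245 at day 14 and 0.156 to 0.322 at day 28. Calls in the same direction numbered 452 to 1329, and 724 at a mean log2 CPM of at least 3, which tests fewer genes. Enriched windows numbered 0 to 1, 0 at 2 Mb and 2 at 500 kb. The SD of slopes was 0.133 to 0.182 and their r between days 0.798 to 0.888. For Bur against Col at day 14 without Col_14d replicate 1, which held most PR1 counts, PR5 reversed to 2.12, PR2 to 2.25 and PR1 to 0.56. Without others they fell as far as -3.58, -3.73 and -9.56. With the replicate block PR5 and PR2 gave 0.35 and 0.62, not called. For the other changes, the cause was not tested. Depth limits genes near the floor, such as FT with 1 to 20 counts per group.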

Other observations

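The tests of the slopes at FLC and at FRI and the genes beside FLC were chosen after the result was seen. Several genes changed with leaf age in more than 1 material. CYP71A13, a camalexin gene, rose in early pools (5.60 ± 0.65) and in Bur (5.38 ± 0.59), and the immune marker NHL10 rose in early pools (4.21 ± 0.69), late pools (5.53 ± 0.76) and Bur (4.06 ± 0.73). NAS3 fell in early pools (-5.20 ± 0.54), late pools (-4.39 ± 0.50), Bur (-5.66 ± 0.65) and Col (-5.94 ± 0.69). The stomatal lineage gene TMM rose in Bur (2.25 ± 0.33) and Col (2.44 ± 0.33). Values are log2 fold changes ± SE with 3 libraries per group, each with an edgeR adjusted p from 0.000826 to 0.00969.

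Whether leaves of late pools were at an earlier stage of ageing at day 28 was tested across 18552 genes. The late against early change at day 28 correlated with the mean change of both parents from day 14 to day 28 with r = -0.212 (rho = -0.223), and with r = -0.245 (rho = -0.303) at day 14, as an earlier stage could give. Genes are not independent replicates. Higher senescence genes in late pools at day 28 (median log2 fold change 0.55, camera adjusted p = 0.0216, adjusted p = 0.746 with an estimated correlation) go the other way, as does the component that parts the days, where late_28d (-64.9 to -46.5) lay beyond early_28d (-43.8 to -7.75). The stage thus stays open.

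FLC was higher in late pools although its own window had slopes of -0.0388 ± 0.064 at day 28 and -0.0867 ± 0.049 at day 14. AT5G05060 and AT5G15360, on both sides of FLC, are among the 97 genes from which Bur shares were read. They had lower Bur shares in late than in early pools (0.497 against 0.909 and 0.597 against 0.816 at day 14, 0.333 against 0.865 and 0.553 against 0.836 at day 28). This goes against a higher share of Bur alleles at FLC as the source. The window that holds FRI had slopes of 0.199 ± 0.037 and 0.130 ± 0.026, so that Bur alleles in that region could raise FLC in late pools. This does not single out FRI, since 36 of 58 windows at day 14 and 37 of 59 at day 28 lay above 0 by more than 2 SE. Genotypes of the lines were not used here. FRI transcript levels themselves were not called in late against early pools (-0.17 ± 0.21 at day 14 and 0.10 ± 0.21 at day 28, edgeR adjusted p = 0.811 and 0.742).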
